A study of Arabidopsis thaliana with 6 samples.

How the data were processed

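The deposited data comprised 6 Affymetrix Arabidopsis arrays, 3 of wild type (Col-0) and 3 of plants overexpressing ERF96. Per the labels' protocols, plants grew for 4 weeks on a soil and perlite mix at 22 °C with 8 h of light and 16 h of darkness, and leaf RNA was taken with Trizol and turned into biotin-labelled cRNA. Per the labels, the RNA came from 3 independent experiments. Groups and replicate numbers were taken from the sample titles.

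The deposited table held 1 linear intensity value per probe set and array, for 22810 probe sets. On each array the mean of the intensities, after trimming 2% from each end, lay at 500, which shows that the arrays had been scaled to a common level before they were deposited. The summary algorithm was not given in the sources used here, and the table held no detection calls. No probe set could therefore be called above or below background. Between 15.5% and 19.6% of the probe sets of an array lay below an intensity of 16. The number of arrays, 3 per genotype, limits the precision of every value.

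The 64 control probe sets were left out of all tests, which left 22746. Of these, 13513 had 1 gene in the platform annotation used here, 503 had several and 8730 had none. The RefSeq table of assembly TAIR10.1 gave a locus for 13436 probe sets, covering 13286 loci. The build behind the array annotation was not given in the sources used here, so no coordinates are printed. Only 14.1% of protein-coding loci with a RefSeq symbol were matched, against 63.1% of those without a symbol. Well-studied genes were thus under-represented among the matched loci. Of the 328 members of the gene lists 59 were matched, and only these are called measured here. The others may lie among the probe sets with several genes or none. Their absence is a gap of the annotation and says nothing about their levels. No gene was named from a probe set with several genes or none.

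Differences were computed on log2(intensity + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets, with a threshold of 0.05. Fold changes are on this offset scale and understate the change of genes with low intensity. Before the data were examined, 23 gene lists, the test, the alternatives and the rule for named genes were fixed. The rule took ERF96, the 12 largest rises and 12 largest falls among probe sets with 1 gene that passed the test with no overlap between genotypes, and the 4 list members of lowest p per list. In the list of ERF-branch defence genes every measured member was named. Lists were tested with camera at a preset inter-gene correlation of 0.01 over 13285 loci, with the brightest probe set per locus and without ERF96. A list needed at least 3 measured members, a minimum set after the data had been seen. By it 10 lists were tested, 10 had 1 or 2 measured members, and 3 (JAZ repressors, epidermis and trichome markers, vascular markers) had none.

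The replicate numbers were checked for pairing through the correlation of each array's deviations from its genotype mean. Arrays with the same number correlated at 0.365, 0.558 and 0.409, and the highest correlation between different numbers was 0.0690. Every pair lay over 0.1, so the numbers pair the samples. The pairing comes from this check and from the shared numbers in the titles. The fit fixed beforehand had no block. Values from a fit with the replicate number as a block are given where they change a call or move a count by over 1.5 times.

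The alternatives fixed beforehand were the replicate block, quantile normalization, median-centred arrays, leaving out the dimmest 40% of probe sets, an intensity trend with a robust prior, array weights, 1 probe set per gene, offsets of 1 and 64, adjusted p thresholds of 0.01 and 0.1, leaving out each array, and 3 other list tests. The procedure was tested on simulated data, with 200 of 22746 probe sets changed in each of 10 runs. It recovered 7.2% of changes of 1 on the log2 scale, 89.0% of changes of 2 and 99.6% of changes of 4, and 4.36% of its calls were false. With the replicate block the shares were 3.2%, 82.2% and 99.0%, with 5.05% false. The simulated noise and pair effects were drawn independently for each probe set, with 1 common variance of the pair effects. All simulated changes were upward. The block lowered recovery there, whereas on the real arrays it raised the calls from 16 to 49. The simulated pairing thus does not match these arrays, and the shares hold for the simulated setting only. Figures were drawn with matplotlib 3.10.9.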

Results

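Transcript levels were measured in leaves of wild-type Arabidopsis (Col-0) and of plants that overexpressed ERF96, with 3 arrays per genotype. ERF96 (AT5G43410) encodes a transcription factor of the AP2/ERF family, group IX, whose members include regulators of jasmonate and ethylene defence responses. The comparison asked which leaf transcripts differ when ERF96 is overexpressed. Arrays correlated with each other between 0.939 and 0.975 over all probe sets on the log2 scale.

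ERF96 itself had an intensity of 8.70 ± 3.84 (SD, n = 3) in wild type and 872 ± 170 (SD, n = 3) in the overexpressor. The log2 difference was 5.16 with a standard error of 0.23, a 35.7-fold increase (limma, adjusted p = 0.000662). The wild-type mean lay below the offset of 16, so the offset sets this size: the log2 difference was 6.54 with an offset of 1 and 3.67 with 64, and passed with both. All 3 overexpressor arrays lay above all wild-type arrays, as the array titles state.

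Beside ERF96, 8 named genes rose, 5 of which encode a glucanase, chitinase family proteins, an osmotin-like protein and a relative of PR-1. AT4G16260, annotated as a glucan endo-1,3-beta-glucosidase, rose 103-fold, from 134 ± 94.0 to 12776 ± 4416 (SD, n = 3 each; limma, adjusted p = 0.0220). Its log2 difference was 6.69, and 5.92 without wild type replicate 1, where the intensity was 25.3 against 190.5 and 185.6 in the other wild-type arrays. AT2G43590 of the chitinase family rose 93.8-fold, from 87.5 ± 16.2 to 9889 ± 2988 (SD, n = 3 each; limma, adjusted p = 0.000623). OSM34, an osmotin-like protein, rose 20.5-fold from 23.7 ± 14.5 to 792 ± 307 (adjusted p = 0.0199), and the chitinase family gene AT2G43580 rose 16.1-fold from 12.5 ± 8.03 to 472 ± 248 (adjusted p = 0.0294). AT2G19970, of the family that holds PR-1, rose 4.23-fold from 11.8 ± 5.40 to 101 ± 12.1 (adjusted p = 0.0404). Its wild-type mean also lay below the offset, and its log2 difference of 2.08 became 3.08 with an offset of 1 (adjusted p = 0.137) and 1.12 with 64 (adjusted p = 0.0809). AT2G43580, whose wild-type mean was also below 16, went from 4.01 to 5.15 (adjusted p = 0.0883) and 2.71 (adjusted p = 0.141), and OSM34 from 4.36 to 5.18 (adjusted p = 0.121) and 3.24, where it passed.

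A pair of jasmonate-induced oxygenases, enzymes that hydroxylate and thereby inactivate jasmonic acid, rose as well. JRG21 (AT3G55970) rose 7.41-fold, from 7.07 ± 3.54 to 157 ± 39.5, and AT5G05600 rose 5.96-fold, from 117 ± 27.3 to 767 ± 52.8 (SD, n = 3; limma, adjusted p = 0.0199 for each). JRG21 had a wild-type mean below the offset, and its log2 difference of 2.89 became 4.34 with an offset of 1 (adjusted p = 0.0760) and 1.62 with 64 (adjusted p = 0.0647). AT3G23550, a transporter of the MATE family, rose 34.7-fold from 118 ± 89.2 to 4495 ± 2758 (adjusted p = 0.0413). QQS (AT3G30720), an orphan gene that affects starch content and the allocation of carbon and nitrogen, was the only probe set that fell in the fit without the block. Its intensity was 1265 ± 106 in wild type and 212 ± 51.4 in the overexpressor, a log2 difference of -2.51 with a standard error of 0.22 (adjusted p = 0.0199), in 1 overexpressor genotype set against 1 wild type. With an offset of 1 AT3G23550 (adjusted p = 0.126), AT4G16260 (adjusted p = 0.121), AT5G05600 (adjusted p = 0.0765) and QQS (adjusted p = 0.0851) did not pass, and AT3G23550 did not with 64 either (adjusted p = 0.0911).

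**Figure D1:**
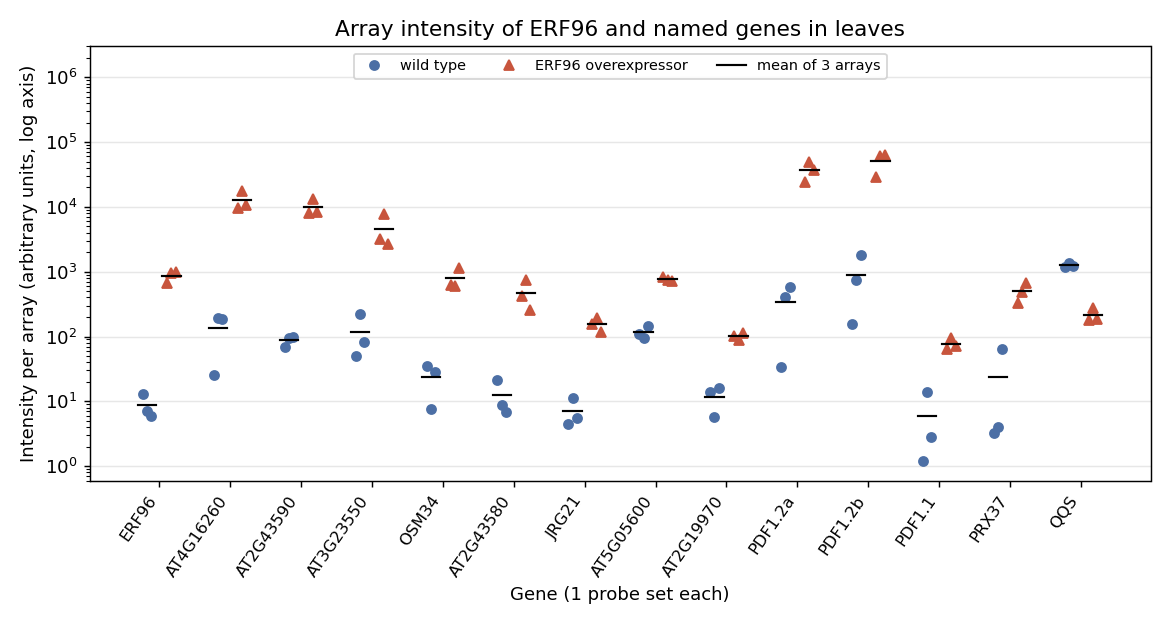
Intensity per array on a log axis for ERF96 and 13 other named genes, with 1 point per array, wild type as circles, the ERF96 overexpressor as triangles and the mean of 3 arrays as a bar. ERF96 lay between 6.0 and 13.1 in wild type and between 678.9 and 997.2 in the overexpressor, and QQS was lower in all 3 overexpressor arrays. PDF1.2a, PDF1.2b, PDF1.1 and PRX37 passed the test with the replicate block and not without it.

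In all, 16 of 22746 probe sets differed between the genotypes (limma, adjusted p under 0.05), 15 higher and 1 lower in the overexpressor, each by at least 2-fold. With the replicate block 49 differed, 48 higher and 1 lower, among them all 16. Of the 16, 10 had 1 gene and 6 had no gene name here. Of the 49, 27 had several genes or none here, so list members may be among them. The log2 differences of the 16 reached 7.36, in a probe set without a gene name here. At an unadjusted p under 0.05 there were 1625 probe sets, 615 higher and 1010 lower, and with the replicate block 2903, 1126 higher and 1777 lower, against 1137 expected by chance. The median of all log2 differences was -0.06, and how far this adds to the lower counts was not tested. The count of 16 fell to 4 without wild type replicate 1 or 2, to 3 without wild type replicate 3 or overexpressor replicate 1, to 5 without overexpressor replicate 2 and to 2 without overexpressor replicate 3. ERF96 and AT2G43590 passed in each of these 6 fits. AT4G16260 passed only without wild type replicate 1 (adjusted p = 0.00954) and QQS only without overexpressor replicate 2 (adjusted p = 0.0420). The other 6 named rises passed in none of them. These fits had no replicate block and fewer arrays, so a lost call need not mean that 1 array carried the difference. With the block and all arrays, all 16 passed.

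Among ERF-branch defence genes, which respond to jasmonate and ethylene together, 6 of the 10 listed were measured. Of these 6, 1 rose in the fit without the block. This was OSM34, while 4 rose with the replicate block and 5 passed when adjusted over the list alone. The plant defensin PDF1.2a had an intensity of 342 ± 282 in wild type and 36995 ± 12127 in the overexpressor, a log2 difference of 7.25 ± 0.87 (SE; adjusted p = 0.0658, and 0.0169 with the replicate block). Its close copy PDF1.2b went from 899 ± 835 to 50881 ± 19359, a log2 difference of 6.28 (adjusted p = 0.0877, and 0.0115 with the block). The suffix of the PDF1.2b probe set marks probes that can also bind related sequences, so signals of near-identical defensins cannot be assigned to 1 copy. The counts above may thus hold 1 signal under both names. PDF1.1 (LCR67) differed by 2.11 (adjusted p = 0.0877, and 0.0209 with the block), but by 3.94 with an offset of 1 and 1.01 with 64. PDF1.4 differed by 0.77 (adjusted p = 0.485) and THI2.1, a thionin, by -0.21 (adjusted p = 0.923). Single wild-type arrays weighed on both PDF1.2 copies. PDF1.2a had 34.2 in wild type replicate 1 against 404.6 and 588.1 in the others, and passed without that array (log2 difference 6.14, adjusted p = 0.0115). PDF1.2b had 154.5 there against 741.3 and 1801.5, and differed by 5.35 without it (adjusted p = 0.0956). Without wild type replicate 3 the differences were 7.94 and 7.06 (adjusted p = 0.0993 for each). PDF1.2a also passed with median-centred arrays (adjusted p = 0.0419) and without the dimmest probe sets (adjusted p = 0.0468), and PDF1.1 with median-centred arrays (adjusted p = 0.0487) and array weights (adjusted p = 0.0379).

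The ERF-branch list as a whole was shifted upward (camera, adjusted p = 1.07e-12, median log2 difference 3.23). At the preset correlation PDF1.2a and PDF1.2b count as nearly independent members although they may share signal, so this p may overstate the evidence. The list had an adjusted p = 0.0159 with an estimated correlation, 0.00136 with fry, a self-contained test, and 0.0125 with camera on ranks at the preset correlation. With an estimated correlation and the replicate block, joined after seeing the data, it had an adjusted p = 0.165, which ends the call.

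In the list of chitinases, glucanases, peroxidases and polygalacturonase inhibitors, the 10 measured members were 7 of the chitinase family and 3 peroxidases, and 2 rose, both of the chitinase family (AT2G43590 and AT2G43580). With the replicate block, and when adjusted over the list alone, 3 rose, and with both 5 passed, the further ones being CHI, named after its values were seen, at 1.85 (adjusted p = 0.0156; 0.88 without wild type replicate 1) and AT2G43620 (adjusted p = 0.0196). The third gene was the peroxidase PRX37 (AT4G08770), at 24.1 ± 35.6 in wild type and 496 ± 168 in the overexpressor, a log2 difference of 3.97 (adjusted p = 0.125, and 0.0209 with the block), which became 5.42 with an offset of 1 and 2.69 with 64. It passed without wild type replicate 3, where its intensity was 65.2 (log2 difference 4.65, adjusted p = 0.0434). The chitinase family gene AT2G43620 differed by 1.60 (adjusted p = 0.621; 1.12 to 2.13 with any 1 array left out). With the block, neither CHI (limma, adjusted p = 0.240) nor AT2G43620 (adjusted p = 0.261) passed over all probe sets. The list was shifted upward (camera, adjusted p = 6.39e-08, median 1.26), with an adjusted p = 0.0584 with an estimated correlation and an adjusted p = 0.165 when the block was added, so the call was lost in both cases. It passed with fry (adjusted p = 0.00489) and with camera on ranks at the preset correlation (adjusted p = 0.0195).

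The other 8 tested lists did not pass. They rested on 3 to 5 measured members each, such as 4 of 29 photosynthesis genes and 3 of 16 group IX ERF factors. A list that did not pass thus says little about its unmeasured members. Among the other ERF factors of group IX, AT5G61590 differed by 1.97, AT5G07580 by 0.77 and AT4G18450 by -0.30 (list adjusted p = 0.211). None passed when adjusted over the list alone, and AT5G61590 did with the replicate block (adjusted p = 0.00265). Over all probe sets AT5G61590 did not pass without the block (limma, adjusted p = 0.777) or with it (adjusted p = 0.145). Its log2 difference was 3.16 without wild type replicate 2 and 1.17 without overexpressor replicate 2. With the block, a trend and a robust prior, a fit chosen after seeing the data, it passed over all probe sets (adjusted p = 0.0195). This list passed when both arrays of replicate 2 were left out (adjusted p = 0.0200), an alternative chosen after seeing the data, and had an adjusted p = 0.521 with an estimated correlation and all arrays. The photosynthesis genes RCA, PSAE-1, LHCB4.1 and LHCB4.2 differed by 0.42, 0.32, 0.29 and 0.07 (list adjusted p = 0.142). Their list passed without wild type replicate 1 (adjusted p = 0.0337) and without overexpressor replicate 1 (adjusted p = 0.000933). All 4 were lower in pair 1, by -0.41 to -0.55, and higher in the other pairs, and with an estimated correlation and all arrays the list had an adjusted p = 0.829.

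In the list of abscisic acid, drought and cold genes, COR15A differed by 1.03, COR15B by 0.55, LEA4-5 by -0.38 and COR47 by -0.40 (list adjusted p = 0.715). COR15B was highest in replicate 2, at 7648 in wild type and 10289 in the overexpressor against 1947 and 1705, and 2086 and 3736, in the other arrays. Not all members followed, as LEA4-5 had 131.2 in wild type replicate 2 against 131.9 and 140.2. The senescence genes WRKY53, WRKY6 and SAG29 differed by 0.98, 0.22 and -0.64 (list adjusted p = 0.715), and WRKY53 passed when adjusted over the list alone with the replicate block (adjusted p = 0.0260; log2 difference 0.39 without overexpressor replicate 3). Over all probe sets WRKY53 did not pass without the block (limma, adjusted p = 0.819) or with it (adjusted p = 0.254). The stomatal lineage genes SPCH, MUTE and FMA differed by 0.18, -0.12 and -0.39 (list adjusted p = 0.715). Of the wall growth genes, XTH33 differed by 0.50, EXPA4 by -0.29 and EXPA8 by -0.56 (list adjusted p = 0.922), with a test direction upward although the median and mean were below 0. The anthocyanin genes AT4G14090 and UF3GT differed by -0.21 and -0.32 and DFR by -0.000683 (list adjusted p = 0.947). The reference genes PEX4, AT4G34270 and AT2G28390 differed by 0.25, -0.02 and -0.17 (list adjusted p = 0.750), with a median of -0.02, a mean of 0.02 and a test direction upward.

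None of the 16 measured members of the lists with 1 or 2 members passed (limma, smallest adjusted p = 0.529, and 0.155 with the replicate block). With the block, a trend and a robust prior STZ did (adjusted p = 0.0285). Adjusted over the list alone, 2 of them passed, OPCL1 of jasmonate synthesis at 1.17 (adjusted p = 0.0180) and the stress zinc finger gene STZ at 1.60 (adjusted p = 0.0459). With the replicate block these and others, 5 in all, passed over the list alone. The others were BSMT1 (limma, adjusted p = 0.0149), GRX480 (adjusted p = 0.0388) and CML38 (adjusted p = 0.0344). BSMT1 was dim, at 12.1 ± 15.3 in wild type, below the offset of 16, and 25.5 ± 17.2 in the overexpressor (SD, n = 3), with overlapping arrays. Over the alternatives its log2 difference ran from 0.24 to 1.56. It was the only measured member of its list, so the adjustment left its value unchanged. The value of CML38, in a list with 2 measured members, was also left unchanged. Lists of 1 or 2 members allow little or no adjustment, and these values were not corrected across lists. With any 1 array left out, the log2 difference ran from 0.98 to 1.54 for OPCL1, 1.03 to 2.02 for STZ, 0.30 to 1.04 for BSMT1, 0.27 to 1.71 for GRX480 and 0.43 to 1.28 for CML38. Of the jasmonate and ethylene genes, JMT differed by -0.15, BSMT1 by 0.62, EIN3 by 0.16 and RTE1 by -0.13. The salicylate genes GRX480 and SAG101 differed by 0.92 and 0.14, and the touch gene CML38 by 0.87. Glucosinolate genes differed by 0.14 for UGT74B1, -0.26 for BCAT4 and -0.31 for AT2G31790. The clock gene GI differed by 0.04, the meristem marker CLV3 by 0.10, and the root markers PYK10 and EXPA7 by 0.65 and -0.49.

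**Figure D2:**
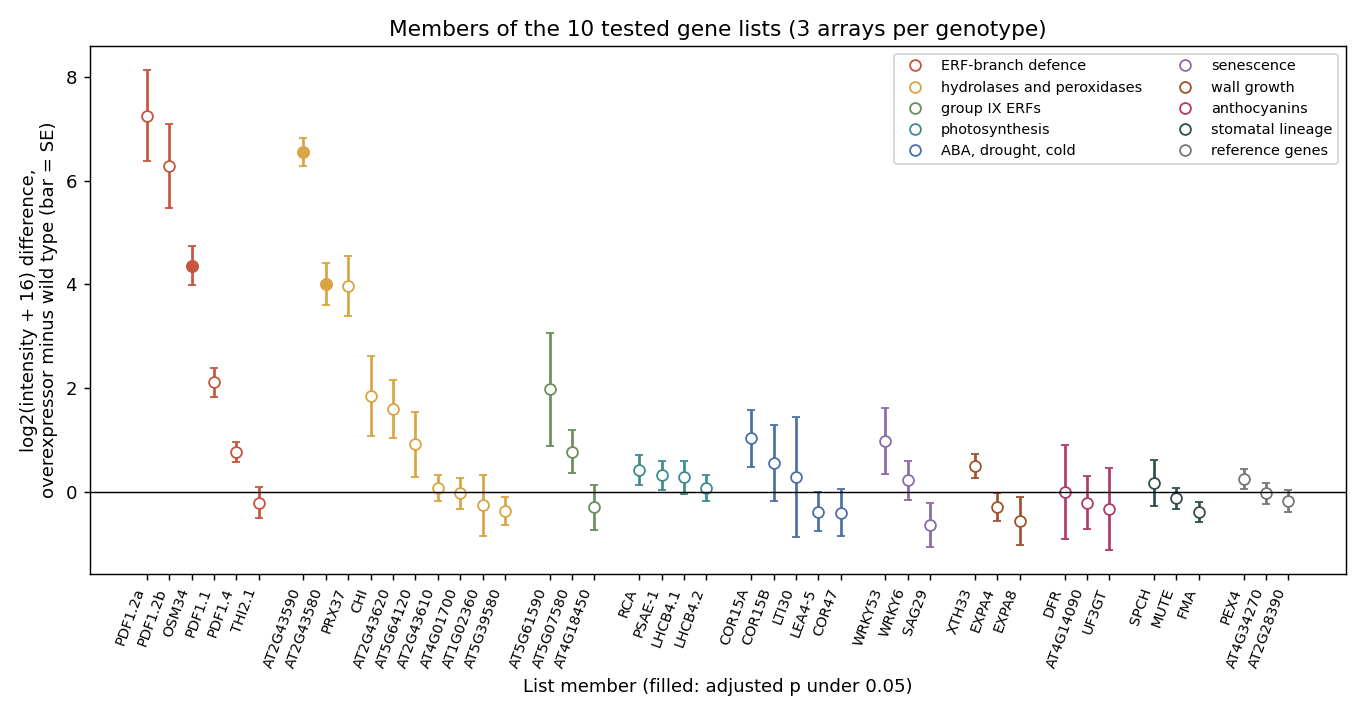
Log2 differences of intensity + 16, overexpressor minus wild type (3 arrays each), for the measured members of the 10 tested lists, with standard errors as bars. Filled points had an adjusted p under 0.05 in the fit without the block: OSM34, AT2G43590 and AT2G43580. The reference genes lay between -0.17 and 0.25.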

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

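The control probe sets were looked at after the main results had been seen. They took no part in the comparison between the genotypes, and none of their differences was tested. The 25S ribosomal RNA control had an intensity of 3549 ± 597 in wild type and 5637 ± 1437 in the overexpressor (SD, n = 3), a log2 difference of 0.65, with all 3 overexpressor arrays above all wild-type arrays. The control for the 5′ part of the GAPDH transcript, at 9629 ± 730 and 11654 ± 1285, differed by 0.27 in the same way. An older GAPDH 3′ control went the other way, at 5346 ± 697 and 3763 ± 481. Of 64 control probe sets, 2 were higher and 11 lower on all 3 overexpressor arrays, and 9 of the 11 were of bacterial transcripts. Chance would give 3.2 in each direction if probe sets were independent. They are not, as several share a transcript, such as lys, so the counts do not measure an excess. Some were also dim, such as LysX-5 at 15.2 in wild type and 3.3 in the overexpressor. With median-centred arrays the counts were 3 and 9.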

How the results depend on the processing

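The alternatives without replicate 2, and those that join the replicate block to an offset of 64, to a trend with a robust prior or to an estimated correlation, were chosen after seeing the data. ERF96 kept its direction and passed in all alternatives but 1: with the replicate block and without both arrays of replicate 2 it had a log2 difference of 5.05 (adjusted p = 0.0554), with fewer arrays in the fit. The 16 changed probe sets became 49 with the replicate block, 10 with 1 probe set per gene (fewer tested), 2 with an offset of 1, 2 at an adjusted p of 0.01 and 28 at 0.1. They became 2 to 5 without any 1 array and 5 without both arrays of replicate 2. With the block they became 64 at an offset of 64 (60 higher, 4 lower), 192 with a trend and robust prior (157 higher, 35 lower) and 2 without replicate 2. Counts of changes of at least 2-fold, not run at other thresholds of p, were the same except 172 in place of 192. Except where fewer probe sets or arrays entered, the cause was not tested. Shifted lists went from 2 to 1 with an estimated correlation and to 0 with the block added. Over 1089 values of 58 other genes, 995 stayed on their side of the threshold, 74 lost and 20 gained a call, and none reversed, though 47 values of uncalled genes changed sign. AT2G43590 passed in all 19 alternatives, and the other 8 called genes each missed the threshold in some, with highest adjusted p between 0.141 and 0.229. Without detection calls, signal over background limits what can be said of dim genes.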

Other observations

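The tests of bright probe sets, of RNA quality, of single arrays and of QQS, and the genes and gene families named in this part, were chosen after the values were seen. The criteria for bright probe sets, RNA quality and single arrays were also made stricter after their values were seen, and under the first criteria all 3 explanations would have counted as excluded. The rises were already known to be 48 of 49 when the other tests were set. With the replicate block further genes rose that the fit without it did not call. They include AT3G16530, a legume lectin family protein, with a log2 difference of 3.03 (limma, adjusted p = 0.179 without and 0.0171 with the block), the glycosyltransferase UGT71C3 at 3.57 (0.0657 and 0.0391) and the cytochrome P450 gene CYP71B22 at 2.23 (0.298 and 0.0424). AT3G50280, of an acyltransferase family, differed by 2.15 (0.128 and 0.0209).

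Arrays of replicate 2 stood apart in both genotypes. On the first principal component, with 40.2% of the variance, they lay at 43.2 in wild type and 68.6 in the overexpressor, and the other 4 arrays lay below 0. The anthocyanin gene DFR had 1702 in wild type replicate 2 against 199.9 and 177.5 in the other wild-type arrays, and 879.6 against 400.7 and 176.0 in the overexpressor. The cold-responsive gene LTI30 had 2267 against 164.3 and 185.4, and 1894 against 175.5 and 398.2.

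Called genes such as PDF1.2a and AT2G43590 were nearly all higher in the overexpressor, with 48 rises and 1 fall in the fit with the replicate block. The scaling of each array was weighed by quantile normalization with the block, where 97.7% of 44 calls were rises. The smallest log2 difference called with the block was 1.65, while the array medians ran only from 143 to 164. Quantile normalization thus had little room to turn the share of rises, and the scaling stays open. Falls hidden in dim genes were weighed in the 10479 probe sets with a wild-type intensity of at least 200, where 94.1% of 17 calls were rises (exact binomial 95% interval 71.3% to 99.9%), but calls so one-sided left this little room to come out otherwise, and among changes of at least 2-fold at an unadjusted p under 0.05 with the block 105 were higher and 78 lower there (57.4%, interval 49.9% to 64.6%), so this stays open. With the block, the excess was smaller with a trend and robust prior (157 rises, 35 falls) and turned round at an unadjusted p under 0.05 (1126 higher, 1777 lower). The median of all log2 differences was -0.06, and how far this adds to the lower count was not tested. An effect of ERF96 itself was not tested separately and stays open.

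The array signals of 69 plastid genes had a median log2 difference of -0.53 (-0.53 with quantile normalization, -0.48 with median-centred arrays), with pair medians of -0.88, -0.23 and -0.40, and 39 genes were lower in all 3 pairs. In the scan of 30 sets behind this, 29 of them gene families by symbol, plastid, TRM, GH and RPS (8 genes, all 8 in the plastid set) passed camera with the preset correlation, 0 sets passed with an estimated correlation (smallest adjusted p = 0.729) or fry with the block (smallest adjusted p = 0.155), and 0 plastid genes passed singly. Brightness alone is argued against, as the median lay at percentile 0 of 10000 nuclear lists of matched brightness (1st to 99th percentile -0.07 to 0.13). The plastid genes moved together (estimated correlation 0.609), so this percentile is no measure of chance. Camera with that correlation gave p = 0.377 for the plastid set. How well the labelling captured plastid transcripts was not tested, so these signals need not follow transcript levels. For degraded RNA, 6 of 9 ratios of 3′ to 5′ control signal were higher in the overexpressor, but the other 3 were all those of pair 1, where the plastid median was lowest, and with the older controls of the same transcripts only 2 of 9 were higher, which runs against it, and since the controls disagree it stays open. For a single array, the median was -0.13 without wild type replicate 1 and between -0.84 and -0.32 without any other array, and -0.35, -0.61 and -0.55 without pair 1, 2 or 3, so it stayed below 0 throughout, and 3 pairs are too few to settle how far wild type replicate 1 sets its size.

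QQS was lower in each of the 3 pairs, by -2.29 in the pair closest to 0. A stock difference at QQS unrelated to ERF96 may account for this, since its level is known to differ between Col-0 stocks. The sample titles do not name the stocks used. With 1 overexpressor genotype set against 1 wild type, a stock difference and an effect of ERF96 cannot be told apart.

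Other splits of the 6 arrays into 3 and 3 number 10 with the real one. The real split called 16 probe sets and the highest other 0, for all changes and for those of at least 2-fold, so 1 split gave a result as large. The real split shifted 2 lists and the highest other 2, so 2 splits gave as many, the other one setting wild type replicates 1 and 3 and overexpressor replicate 1 against the rest, and 3 further splits shifted 1 list each. With 4 of the 9 other splits shifting a list, this list test at its preset correlation also calls lists where genotypes are mixed. Each other split mixes the genotypes unevenly, so part of any genotype difference remains in it. These list calls are therefore not shown to be false. Of the 4 splits that part all 3 pairs, 1 gave as large a count with the replicate block, the real one with 49 against 0 for the highest other. These splits are too few for a share under 0.05.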
